A study of Mus musculus with 32 samples.

How the data were processed

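The series holds 32 two-colour microarrays of kidney RNA from C57BL/6 mice, a standard inbred laboratory strain, at 10 stages of late fetal and postnatal development. Per the labels, kidney total RNA was labelled with Cy5 and a universal mouse reference RNA, common to all arrays, with Cy3, and no dye swap is named. Embryonic day 19 (E19) and postnatal days 1, 5, 7, 10, 14, 21 and 28 (P01, P05, P07, P10, P14, P21, P28) have 3 arrays each, and P03 and P35 have 4. Stages were taken from the age given for each sample, and replicate numbers only name arrays. A protocol text repeated for the samples speaks of ureteral obstruction, whereas each sample's source name says normal kidney, and the source names were followed. The labels do not say how many animals the arrays of a stage came from. At E19, P03, P05, P07, P10, P28 and P35, Xist and Eif2s3y differed in opposite directions between arrays, so the arrays of these stages did not all come from the same animal. P-values measure the spread between these arrays.

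The values used are the deposited values, with 1 ratio per probe and array, read here as log10. The unit is not stated in the sources used here and was settled from the values, which run from -3.25 to 4.00. Read as log2, the largest ratio of any probe to the reference would be 16-fold, whereas a scanner covers several orders of magnitude. All values were multiplied by 3.32 to give log2 ratios. Were the table in log2 after all, every log2 change would be smaller by that factor, while directions and adjusted p-values would stay. Feature extraction, background correction and dye normalization are not given in the sources used here. The direction of the ratio is not stated either, and was read from gene lists fixed beforehand. The median log2 ratio of the proximal tubule list lay between 4.38 and 6.31, that of the thick ascending limb list between 3.61 and 5.65 and that of the podocyte list between 0.95 and 3.05, above 0 on 32 of 32 arrays for each list. The ratio was therefore taken as kidney over reference. Every array had a median log10 ratio of 0 over all probes, and of -0.0503 to -0.00593 without exact zeros, so arrays look centred, while genes were not centred. Correlations between arrays over genes ran from 0.732 to 0.982. No pair of arrays was identical: the smallest median absolute log2 difference between 2 arrays was 0.158.

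Between 10.8% and 23.1% of the values on an array were exactly 0. The labels do not say what a 0 stands for. Such values were treated as not measured, a choice made after seeing the data, and keeping them as ratios of 0 is 1 of the alternatives. Spot intensities were not used here, so neither background nor saturation could be checked and the precision is limited by the number of arrays. Of 45220 probes, 202 had no value. In the platform's annotation 33653 probes have 1 gene symbol, 56 have several and 11511 are not listed and are unnamed here. Entrez identifiers matched 18966 of 19087 genes in the reference gene table, and 0 symbols needed updating. Probes with several symbols were left out, which gave 18999 genes with a value, 15149 of them measured on all arrays. A gene's value is the mean of its probes that were measured on all 32 arrays. Where it had none, the probe measured on most arrays was used. The design had planned the mean of all probes, which missing values would have made uneven between arrays. Of the genes tested, those with probes that passed the test in opposite directions numbered 68 of 7360 with several probes for P35 minus E19, 1 of 7349 for P01 minus E19, 3 of 7198 for P07 minus P01, 5 of 7245 for P21 minus P07 and 0 of 7394 for P35 minus P21 (limma at probe level).

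Tests used limma 3.58.1 in R 4.3.3, with the data.table package (1.17.8), and figures used matplotlib 3.10.9 in Python 3.11.15. A linear model with 1 mean per stage was fitted to the log2 ratios of all 32 arrays, with moderated variances, so that the 10 stages share 1 estimate of the spread. A moderated F test asked whether a gene differed between any stages, among genes measured on at least 2 arrays of every stage. Pairwise tests covered the whole span (P35 minus E19) and 4 shorter spans that tile it, among genes measured on at least 2 arrays of both stages. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. The shorter spans share arrays with their neighbours, and no overlap of calls between spans was tested.

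There were 34 gene lists with 472 genes: cell types and precursors of the kidney, cell division and metabolism, hormone systems, sex, sample handling, and other tissues that a kidney sample could hold. List shifts were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 170 tests, and again with the correlation estimated from the data. Member counts are given over all genes tested and adjusted over the list alone. Timing was described for genes past the F test by the single step between neighbouring stages that best fits the arrays, kept where R squared was at least 0.6, with the share of steps from P10 to P14 or later. Genes are named by a fixed rule. It takes per span the 5 rises and 5 falls of largest log2 change among genes past the threshold whose arrays do not overlap, without clone names. It adds the 2 members with the smallest adjusted p of the 8 lists with the smallest camera p, the leading member of each list for other cell types, sex or handling, and the best-fitting step gene per interval and direction. Members may be named to identify a count of 5 or fewer. Comparisons, lists, the naming rule and most alternatives were fixed before the data were examined.

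Image numbers in the labels fall into 3 runs, which were treated as a possible batch. After stage means were removed, the first principal component held 41.9% of the variance between arrays, and image run accounted for 72.5% of it. Counts and list shifts are therefore given also with the run as a block, and counts within runs 2 and 3. Runs and stages are unevenly crossed: no P07 array is in run 3, no P28 or P35 array in run 1, and no P01, P03 or P21 array in run 2. Other alternatives were array medians subtracted, quantile normalization, the most variable probe per gene, 1 array per stage as the minimum, genes measured on all arrays, only the 2 stages compared, the image month as a block, array weights, a robust prior with trend, a minimum of 2-fold, and each array left out in turn. The block named image month sets run 3 against runs 1 and 2. Added after seeing the data were zeros kept as ratios, the Xist log2 ratio of each array as a covariate, and the median of the adipose list as a covariate. Sex is not labelled, and no array was assigned a sex.

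The scripts were tested on simulated data with independent noise and no batch. Of genes seeded with a 2-fold change, 31.3% were recovered for P35 minus E19, 35.8% for P01 minus E19, 31.3% for P07 minus P01, 40.3% for P21 minus P07 and 37.3% for P35 minus P21. For 4-fold changes the shares were 75.8%, 83.3%, 75.8%, 78.8% and 78.8%, and for 1.5-fold changes 11.9%, 4.48%, 5.97%, 4.48% and 7.46%, in the same order. Wrong calls numbered 4, 3, 2, 2 and 8 among 16816, 16760, 16670, 16738 and 16841 genes. The F test recovered 62% of 2-fold and 87% of 4-fold steps among 16334 genes, and 100% of the 51 and 85 steps kept lay in the seeded interval. A seeded straight line over days with a 4-fold span was placed between P10 and P21 for 86.2% of the 138 genes kept.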

Results

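The data describe gene expression in whole mouse kidneys from embryonic day 19 (E19) to postnatal day 35 (P35), as log2 ratios of kidney RNA to a common reference RNA. E19, P01, P05, P07, P10, P14, P21 and P28 had n = 3 arrays each, and P03 and P35 had n = 4. Between 16195 and 17982 genes were measured on an array, and the number of arrays limits the precision. Changes are log2 changes, later stage minus earlier stage, with standard errors after ±, and p-values are adjusted values from limma's moderated test or camera. Values with the image run as a block, a possible batch, stand beside the results.

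The question of the series was how kidney gene expression changes as the organ matures after birth. Of 16334 genes tested, 7138 (43.7%) differed between stages by the moderated F test, and 9533 did with the image run as a block. Mest, an imprinted gene of fetal growth, fell from a log2 ratio of 6.72 ± 0.21 (SD) at E19 to 1.06 at P35. Nephron progenitor genes fell mainly within the first postnatal week, cell division and matrix genes fell mainly from P07 to P21, and genes of mitochondrial energy metabolism rose between E19 and P35.

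**Figure D1:**
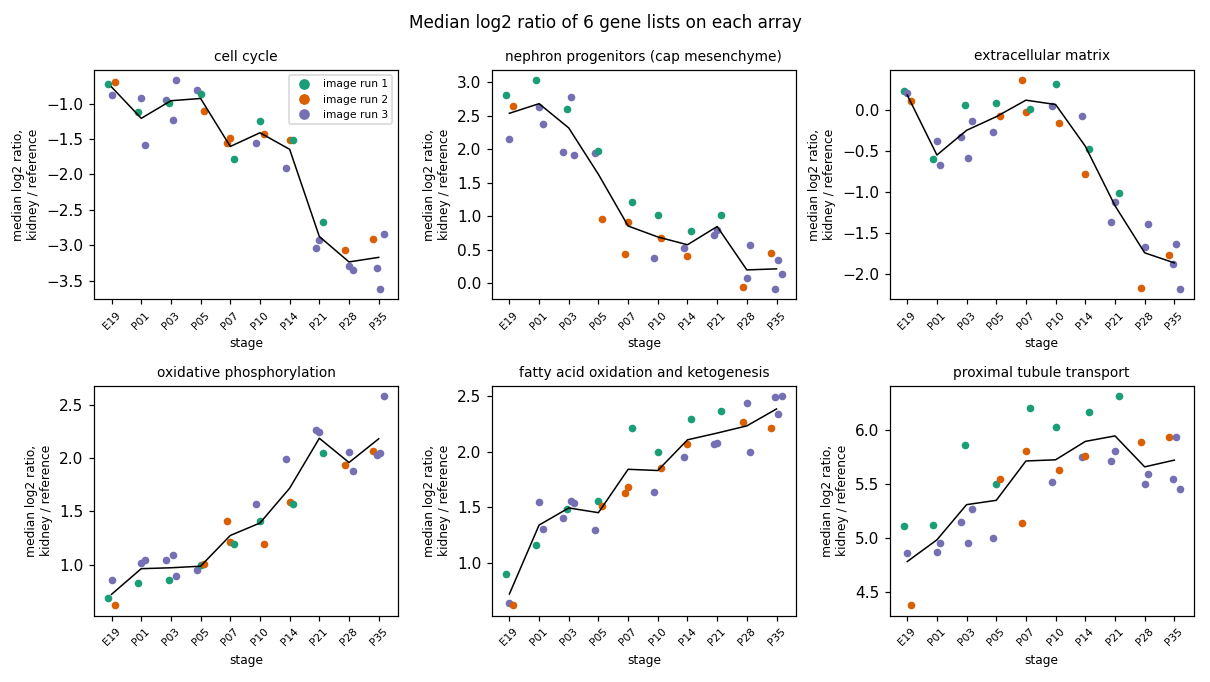
Median log2 ratio of 6 gene lists on each array (points, coloured by image run) by stage, with stage means as lines. The cell cycle list had a mean of -0.76 at E19 and -3.17 at P35, and the oxidative phosphorylation list 0.72 and 2.19.

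Across the whole span, P35 minus E19, genes of nephron formation, cell division and fetal growth fell, and genes of oxidative metabolism rose. The largest rises were in Akr1c14 (6.65 ± 0.78), an aldo-keto reductase that acts on steroids, Acot12 (6.51 ± 0.50), a thioesterase that splits acetyl-CoA, Enpp6 (6.15 ± 0.46), a choline phosphodiesterase, Cyp2c23 (5.89 ± 0.41), an arachidonic acid epoxygenase, and Glod5 (5.79 ± 0.24). The largest falls were in Nts (-7.72 ± 0.73), the precursor of neurotensin, Cstdc6 (-6.47 ± 0.74), Kcnmb4 (-6.44 ± 0.44), a potassium channel subunit, Igf2 (-6.30 ± 0.29), a fetal growth factor, and Afp (-6.06 ± 0.34), alpha-fetoprotein. In all, 3625 genes rose and 3258 fell among 17117 tested.

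Precursor cells and growth formed the falling side. Of 14 nephron progenitor genes tested, 10 fell, 0 rose and 4 did not pass (0 up and 11 down when adjusted over the list alone; list median -2.27, -2.33 with the block, adjusted p = 7.20e-06). Of 11 ureteric bud tip genes 6 fell (8 adjusted over the list alone) and 1 rose (median -1.73, adjusted p = 0.00481). The riser was Slco4c1 (1.52), an organic anion transporter. Among 11 stromal progenitor genes 8 fell and Ntn1 (2.16), a guidance cue, rose (8 and 1 also adjusted over the list alone, median -2.32, adjusted p = 0.000119). Of 14 early nephron genes 8 fell (9 adjusted over the list alone) and Papss2 (3.08), a sulfate donor synthase, rose. That list had a median of -1.53 and adjusted p = 0.00125, but adjusted p = 0.136 with an estimated correlation. All 29 cell cycle genes tested fell, also adjusted over the list alone (median -2.47, -2.34 with the block, adjusted p = 1.92e-20), with Aurka (-2.45 ± 0.20) and Tpx2 (-2.66 ± 0.21), both of the mitotic spindle. Of 14 imprinted growth genes 13 fell on either adjustment (median -2.60, adjusted p = 2.16e-11), led by Mest (-5.66 ± 0.17). Of 23 extracellular matrix genes 18 fell (19 adjusted over the list alone, median -1.46, adjusted p = 1.01e-08), among them the fibrillar collagens Col1a1 (-2.73 ± 0.24) and Col3a1 (-2.42 ± 0.20). Of 15 ribosomal protein genes 12 fell (14 adjusted over the list alone, median -0.79, adjusted p = 3.15e-05). Apart from the early nephron list, these lists also passed with an estimated correlation.

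Energy metabolism formed the rising side. All 21 oxidative phosphorylation genes tested rose, also adjusted over the list alone (median 1.55, 1.52 with the block, adjusted p = 2.16e-11), with Ndufa1 (1.99 ± 0.21) of complex I and Atp5c1 (1.55 ± 0.18) of the ATP synthase. Of 21 genes of fatty acid oxidation and ketogenesis 19 rose (20 adjusted over the list alone, median 1.54, adjusted p = 9.82e-11), with Acadm (2.74 ± 0.20), a medium-chain acyl-CoA dehydrogenase. Of 19 genes of amino acid and glucose metabolism 16 rose on either adjustment (median 1.86, adjusted p = 2.17e-08), with Khk (3.47 ± 0.19), which phosphorylates fructose, and Prodh (3.45 ± 0.24), which degrades proline. These 3 lists passed with an estimated correlation as well. Of 23 xenobiotic and steroid metabolism genes 16 rose (17 adjusted over the list alone, median 1.30, adjusted p = 5.87e-07), with Cyp4a14 (5.58 ± 0.44) and Fmo2 (2.57 ± 0.21). That call was not kept with an estimated correlation (adjusted p = 0.0523). The adipose list moved in the same direction over this span: 6 of its 7 genes tested rose (also adjusted over the list alone), among them Retn (4.03), while Fabp4 fell (-0.92), for a median of 3.98 (adjusted p = 0.0453). Its call was not kept with the block (median 3.72, adjusted p = 0.104) or with an estimated correlation (adjusted p = 0.551), nor after quantile normalization (3.74) or with Xist as a covariate (3.87). It also ended without E19 array 1 (3.57), E19 array 3 (3.97), P35 array 1 (3.59), P35 array 2 (3.51) or P35 array 4 (3.92), and without P01 array 1, P01 array 3, P07 array 3, P10 array 1 or P21 array 3 (3.98 each). With the adipose list median of each array as a covariate, chosen after seeing the data, 5025 genes passed, 18 fatty acid oxidation and 21 oxidative phosphorylation genes rose, and 16 matrix genes fell. That median was itself higher on all P35 arrays (2.44 to 5.81) than on all E19 arrays (0.81 to 1.32), so a lost call alone does not tell fat from stage.

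Part of the genes of several tubule segments rose. Of 37 proximal tubule transport genes 20 rose and 17 did not pass (21 adjusted over the list alone, 30 with the block; median 1.16, 1.20 with the block, adjusted p = 2.76e-07). Slc6a19 (5.30 ± 0.55), a neutral amino acid transporter, and Slc37a4 (2.14 ± 0.16), the glucose-6-phosphate transporter, led it. Of 12 thick ascending limb genes Egf (4.84), Slc12a1 (1.12), Ptger3 (2.39) and Casr (2.24) rose (4 also adjusted over the list alone, median 0.41, adjusted p = 0.0448). Of 11 distal convoluted and connecting tubule genes 6 rose (7 adjusted over the list alone, median 1.15, adjusted p = 0.00519), and of 13 intercalated cell genes 6 rose on either adjustment (median 0.82, adjusted p = 0.0111). With an estimated correlation these 4 calls were not kept (adjusted p = 0.216, 0.421, 0.372 and 0.449 in that order). The thick ascending limb call also ended without E19 array 2, E19 array 3, P35 array 1, P35 array 2 or P35 array 3 (medians 0.36 to 0.48), after quantile normalization (0.09) and with the adipose covariate (0.29). The distal (0.72) and intercalated (0.57) calls ended after quantile normalization too. Collecting duct principal cells (2 up, 1 down of 12; median 0.20, adjusted p = 0.844) and urea and osmolyte handling (4 up, 2 down of 8; 0.80, adjusted p = 0.821) gave no call, with the same member counts adjusted over the list alone. Nor did podocytes, where Clic5, Col4a4 and Col4a3 rose and Wt1 (-2.74), Cdkn1c, Nes, Kirrel and Cd2ap fell (of 15, on either adjustment; median -0.44, adjusted p = 0.359). Of 8 vitamin D and phosphate hormone genes Dio1, Vdr, Rxra and Cyp24a1 rose (5 adjusted over the list alone, median 0.87, adjusted p = 0.0332, adjusted p = 0.369 with an estimated correlation; not called without E19 array 2, 0.77, or after quantile normalization, 0.50). Of 7 renin-angiotensin genes Agt (2.43), Agtr1a (1.35) and Agtr1b (2.63) rose and Agtr2 (-5.72), the fetal angiotensin receptor, fell, on either adjustment (median 0.78, adjusted p = 0.251).

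Among lists of other cell types, sex and handling, skeletal muscle had 5 genes down and Pvalb (4.08), also a gene of the distal convoluted tubule, up, of 10 (median -1.85, adjusted p = 0.010, adjusted p = 0.380 with an estimated correlation; not called without E19 array 2, -1.12). Smooth muscle and pericytes had 5 of 10 down (6 adjusted over the list alone), with Notch3 (-1.80) first (median -0.95, adjusted p = 0.00356, adjusted p = 0.327 with an estimated correlation). Of 10 male-biased genes 5 rose (7 adjusted over the list alone), led by Cyp4a12a (2.69 ± 0.28; median 1.20, adjusted p = 0.00893, adjusted p = 0.218 with an estimated correlation), and this call also ended after quantile normalization (median 0.65) and with the most variable probe (1.20). The leukocyte list had 5 of 17 up, among them Cd74 (2.40) and H2-Aa (4.34) of antigen presentation, and S100a8 (-4.61) and S100a9 (-2.39), of neutrophils, down (median 0.31, adjusted p = 0.148). No call was given for endothelium (Egfl7 -0.79 down, of 13; median 0.12, mean -0.02, test downward, adjusted p = 0.949), or erythroid cells (Klf1 1.67 up, of 8; median -0.34, mean -0.01, test upward, adjusted p = 0.952). The same held for the adrenal gland (2 up and 2 down of 9, with Pnmt at -1.53, and -0.64 without a call with the adipose covariate; median -0.09, adjusted p = 0.963) and for urothelium (Krt15 1.61 up and 2 down of 9, 1 down adjusted over the list alone, median -0.37, adjusted p = 0.762). Immediate early and heat shock genes had 2 up and 3 down of 13 (1 and 3 adjusted over the list alone), with Dusp1 at 1.63 (median -0.46, adjusted p = 0.482). Clock genes had 5 up and Cry1 (-2.48) down of 12, with Tef at 2.62 (median 0.60, adjusted p = 0.101). Interferon-induced genes had Ifit3 up and Bst2 and Isg15 down of 13 (median 0.30, adjusted p = 0.957). Sex-linked genes had 0 of 4 past limma's test, where Uty differed by 1.55 (adjusted p = 0.565; list adjusted p = 0.952). Xist was high on some arrays and low on others at both stages, and Eif2s3y of the same list went the opposite way. This result therefore cannot tell whether sex was balanced between the stages. Member counts of the skeletal muscle, leukocyte, endothelium, erythroid, adrenal, clock, interferon and sex-linked lists were the same adjusted over the list alone.

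For P35 minus E19, 6883 of 17117 genes passed, 8485 with the block, 6735 of them shared, and 4475 changed at least 2-fold. With only these 2 stages compared 5919 passed, with array weights 9294, within image run 3 5634, and within run 2, with 1 array per stage, limma gave 0 (3335 at an unadjusted p under 0.05). Single arrays of the stages did not overlap for 43.1% of genes, where chance gives 5.71% for genes measured on all these arrays. Chance gives more for genes with missing values, here and in the spans below. Of the 21 called lists all but the adipose list were called with the block.

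**Figure D2:**
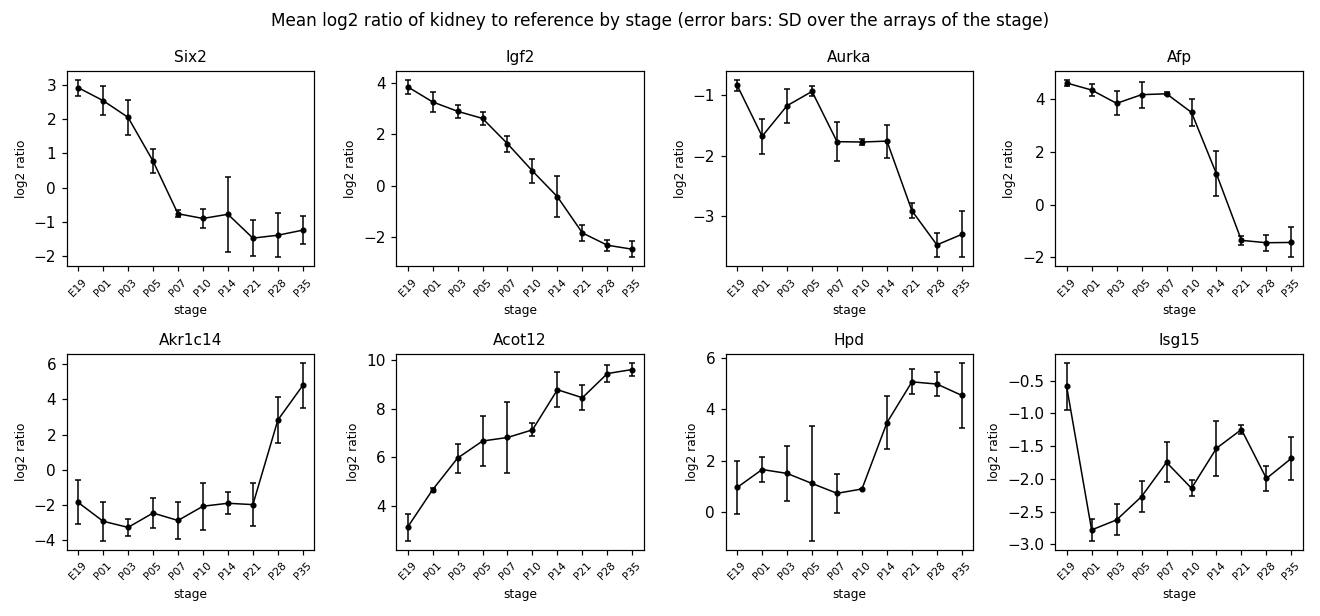
Mean log2 ratio by stage of 8 named genes, with SD as bars. Igf2 fell from 3.85 at E19 to -2.46 at P35, and Acot12 rose from 3.11 to 9.62.

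Over birth, P01 minus E19, genes induced by interferon fell and genes of fatty acid oxidation rose. Of 13 interferon-induced genes Isg15 (-2.19 ± 0.23), Usp18 (-1.30 ± 0.24), Bst2 and Oasl2 fell (5 adjusted over the list alone, median -0.84, -0.91 with the block, adjusted p = 4.95e-09). Of 21 fatty acid oxidation genes Ehhadh (1.49 ± 0.24), of peroxisomes, Cpt1a (1.16 ± 0.20), which passes fatty acids into mitochondria, and Cpt2 rose (5 adjusted over the list alone, median 0.44, adjusted p = 2.76e-07). The largest rises included Cyp4a14 (3.50 ± 0.47), a fatty acid hydroxylase, Angptl4 (2.62 ± 0.45), an inhibitor of lipoprotein lipase, and Spata48 (2.61 ± 0.29). Of 7 renin-angiotensin genes Agtr1a (1.22 ± 0.21), an angiotensin receptor, rose on either adjustment (median 0.47, adjusted p = 0.00267). These 3 lists also passed with an estimated correlation. Lum (-3.17 ± 0.46), a matrix proteoglycan, Myh3 (-2.77 ± 0.44), embryonic myosin, and Wdr78 (-2.21 ± 0.38) fell most among genes that passed without each array. Gnal (3.14 ± 0.74), Mid1 (2.83 ± 0.66), Cyp2a5 (-3.56 ± 0.71) and Gbp6 (-2.89 ± 0.74) also belonged to the largest changes. Gnal did not pass without E19 array 1, E19 array 3, P01 array 2 or P01 array 3 (2.63 to 3.40), and Mid1 without any 1 of the 6 arrays of both stages (2.68 to 2.97). Cyp2a5 did not pass without E19 array 3 or P01 array 3 (-2.98 to -2.92). Gbp6 did not pass without any 1 of 25 arrays, among them all of E19, P01 array 1 and P01 array 3 (-3.27 to -2.58), and Usp18 without P01 array 3 (-1.05). With exact zeros kept as ratios, chosen after seeing the data, Gnal (0.90), Wdr78 (-1.30) and Gbp6 (-2.89) did not pass, and Gbp6 did not with array weights (-1.71) either. With the most variable probe of each gene Agtr1a (1.58) and Cpt1a (1.33) did not pass. Gbp6 also lost its call with array medians subtracted (-2.93), with 1 array per stage as the minimum or a robust prior (-2.89 each), with Xist (-2.87) and with the adipose covariate (-2.88).

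Other lists moved over birth with few members past the test. Of 29 cell cycle genes Aurka (-0.84 ± 0.21) fell (7 adjusted over the list alone, median -0.49, adjusted p = 3.83e-08). Of 19 genes of amino acid and glucose metabolism G6pc (1.51 ± 0.30), of glucose release, and Ddc (1.35 ± 0.30) rose (6 up and 1 down adjusted over the list alone, median 0.57, adjusted p = 0.000602). Of 23 xenobiotic genes Cyp4a14, Gsta2 (0.98) and Gsta1 rose (5 adjusted over the list alone, median 0.23, adjusted p = 0.00322). Of 23 matrix genes Mgp (1.20) rose and Lum fell (1 up and 4 down adjusted over the list alone, median -0.20, adjusted p = 0.00339). The oxidative phosphorylation list had 0 of 21 genes past limma's test, also adjusted over the list alone, with a median of 0.21 and adjusted p = 0.00587, and the imprinted list 0 of 14 (1 down adjusted over the list alone; -0.27, adjusted p = 0.0226). Skeletal muscle genes Myh3 and Actn3 (-1.38) fell, of 9 on either adjustment (median -0.97, adjusted p = 5.05e-05), and Cnn1 (-1.77) of smooth muscle, of 10 (median -0.39, adjusted p = 0.0157). With an estimated correlation none of these 8 lists was called (adjusted p = 0.166, 0.187, 0.305, 0.274, 0.284, 0.151, 0.125 and 0.449 in the order given). The adipose list had a median of -0.00081 and 0 of 7 genes past limma's test (adjusted p = 0.952). Values without 1 array ended several of these calls. They were Aurka (14 arrays, among them all of E19, P01 array 2 and P01 array 3; -0.89 to -0.69), G6pc (E19 array 3, P01 array 3; 1.31 to 1.54), Ddc (E19 arrays 2 and 3, P01 array 3; 1.19 to 1.38) and Gsta2 (E19 arrays 1 and 3, P01 arrays 2 and 3; 0.88 to 0.99). Others were Mgp (E19 arrays 2 and 3, P01 arrays 1 and 3; 0.97 to 1.23), Actn3 (E19 arrays 1 and 2, P01 array 3; -1.26 to -1.03) and Cnn1 (E19 arrays 1 and 2, P01 arrays 2 and 3; -1.91 to -1.48). List calls ended for xenobiotic metabolism (0.10) and oxidative phosphorylation (0.18) without E19 array 3, for the imprinted list without E19 array 1 (-0.16) or E19 array 3 (-0.21), and for smooth muscle without E19 array 1 (-0.14) or P01 array 3 (-0.17), or with the most variable probe (-0.35). Aurka did not pass with the most variable probe or a robust prior (-0.84 each) or with Xist as a covariate (-0.78), nor did Actn3 after quantile normalization (-1.31).

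For P01 minus E19, 246 of 16984 genes passed (143 up, 103 down), 681 with the block, which shared all 246. With only these 2 stages compared limma gave 0 (1437 at an unadjusted p under 0.05), so every gene call of this span rests on the spread shared over the 10 stages. Within image run 3 80 passed, 25 of them among the 246, and with array weights 2847. Non-overlapping arrays were found for 15.8% of genes, where chance gives 10.0% for genes measured on all these arrays. The count fell to 134, 125 and 117 without E19 arrays 1, 2 and 3, and to 53 without P01 array 3. The 11 called lists were all called with the block.

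In the first postnatal week, P07 minus P01, nephron progenitor genes fell and the largest rises included genes of fat. Of 14 nephron progenitor genes 9 fell on either adjustment (median -1.72, -1.74 with the block, adjusted p = 1.79e-11), with Eya1 (-3.56 ± 0.37) and Six2 (9.85-fold lower), transcription regulators that keep progenitors undifferentiated. Of 10 ureteric bud tip genes Slco4c1 (-3.05 ± 0.58), Etv4 (-2.46 ± 0.56) and Sox9 fell (5 adjusted over the list alone, median -1.13, adjusted p = 5.37e-05). Of 14 early nephron genes Hes5 (-2.44 ± 0.37), a Notch target, Fgf8 (-2.12 ± 0.35) and Wnt4 fell (4 adjusted over the list alone, median -0.40, adjusted p = 0.00121, adjusted p = 0.136 with an estimated correlation). Elavl4 (-5.06 ± 0.50), Nat8f5 (-4.92 ± 1.11), Dcx (-3.75 ± 0.65), a microtubule protein of young neurons, and Bmper (-3.46 ± 0.38) were the other largest falls. Cox8b (6.63 ± 1.14), Adipoq (6.52 ± 1.19), Ucp1 (5.10 ± 1.12), the uncoupling protein of brown fat, Car3 (4.96 ± 1.01) and Cidea (4.59 ± 0.88) rose most.

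Of 14 imprinted genes Mest (-1.02), Slc38a4 (-1.23), Igf2 and Plagl1 fell (9 adjusted over the list alone, median -0.77, adjusted p = 6.60e-07). Of 15 ribosomal protein genes 5 fell (6 adjusted over the list alone, median -0.45, adjusted p = 1.46e-06), led by Rps6 (-1.24) and Rpl13 (-0.62). Of 21 fatty acid oxidation genes Hadh (1.28), Acot12 (2.16) and Acaa1b rose (5 adjusted over the list alone, median 0.40, adjusted p = 0.00109). These lists, nephron progenitors and ureteric bud tip also passed with an estimated correlation. Of 37 proximal tubule genes 6 rose on either adjustment (median 0.51, adjusted p = 1.11e-05), with Slc13a1 (4.59 ± 0.77), a sulfate transporter, and Cubn (1.04 ± 0.18), of protein uptake. Of 13 intercalated cell genes Slc26a4, Hmx2, Aqp6 and Atp6v1b1 rose on either adjustment (median 0.71, adjusted p = 0.00150). Of 21 oxidative phosphorylation genes Atp5c1, Ndufa1 and Cox6a1 rose (4 adjusted over the list alone, median 0.39, adjusted p = 0.00267). Of 23 matrix genes Lum and Dcn rose (3 adjusted over the list alone; 0.35, adjusted p = 0.0158), and of 19 amino acid and glucose genes Khk and Gatm (3 adjusted over the list alone; 0.34, adjusted p = 0.0323). Of 29 cell cycle genes Mcm7 fell (0 adjusted over the list alone, median -0.26, adjusted p = 0.00144). With an estimated correlation these 6 calls were not kept (adjusted p = 0.305, 0.305, 0.223, 0.380, 0.468 and 0.496). The adipose list rose beside them, with 5 of 7 genes (6 adjusted over the list alone), a median of 4.33 (4.70 with the block), adjusted p = 2.24e-05 and adjusted p = 0.139 with an estimated correlation. Fabp4, abundant in fat and in endothelium, changed by 0.06 (adjusted p = 0.947) from a log2 ratio of 6.34. The adipose list median lay between 0.73 and 2.17 on the P01 arrays and between 5.54 and 6.4 on the P07 arrays, so it nearly follows the stage. A change adjusted for it is less precise, and a lost call alone does not tell fat from other sources. With the adipose median as a covariate, chosen after seeing the data, 269 genes passed and 264 of them were among the 1237. Then 0 fatty acid oxidation genes passed limma's test (list median 0.33, adjusted p = 0.0107), 0 oxidative phosphorylation genes (0.29, adjusted p = 0.0258), 1 matrix gene (0.25, adjusted p = 0.179) and 5 nephron progenitor genes (-1.45, adjusted p = 8.99e-10). The matrix, amino acid and glucose (0.19) and smooth muscle (0.44) lists lost the call. So did the fat genes Cox8b (2.21), Adipoq (1.70), Car3 (1.60), Cidea (0.93) and Ucp1 (0.75), and also Nat8f5 (-5.49), Etv4 (-2.09), Fgf8 (-1.75), Acot12 (1.96), Hadh (1.20), Slc38a4 (-1.17), Rps6 (-1.18), Rpl13 (-0.73), H2-Aa (2.11), Hbb-y (1.34), Cnn1 (0.82), Slc22a30 (0.76) and Pnmt (-0.88). Adipoq, Cidea and Ucp1 belong to the list whose median is the covariate, so their lost calls largely follow from the construction.

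Leukocyte genes H2-Aa (2.07), Cd52, Adgre1 and Lyz2 rose, of 17 (7 adjusted over the list alone, median 0.38, adjusted p = 0.0226), but the call was not kept with the block (adjusted p = 0.0693) or an estimated correlation (adjusted p = 0.372). Smooth muscle had Cnn1 (1.34) up of 10 (3 adjusted over the list alone; 0.48, adjusted p = 0.0448), not kept with the block (adjusted p = 0.0550) or an estimated correlation (adjusted p = 0.536). Pnmt (-1.91) of the adrenal medulla, Tnnt3 (-1.85) of skeletal muscle, Hbb-y (1.53), an embryonic globin, and Slc22a30 (0.90) of the male-biased list passed in lists without a call. Calls that ended without 1 array were Acot12 (P07 arrays 2 and 3; 1.69 to 1.78), H2-Aa (P01 array 2, P07 array 1; 1.64 to 1.73), Rps6 (P01 array 3, P07 array 3; -1.02 to -0.87) and Rpl13 (P01 arrays 1 and 2, P07 array 2; -0.61 to -0.57). The same held for Cnn1 (all P01 arrays, P07 arrays 1 and 2; 1.19 to 1.48), Hbb-y (P01 array 3, P07 arrays 1 and 2; 1.31 to 1.42) and Slc22a30 (P01 arrays 1 and 3, P07 arrays 1 and 3; 0.61 to 0.89). Lists that lost the call were amino acid and glucose metabolism (P01 array 2, P07 array 3; 0.20 to 0.32), the cell cycle (P01 array 2; -0.15), the matrix (P01 array 3, P07 array 3; 0.18 to 0.25), leukocytes (P01 array 2; 0.33), oxidative phosphorylation (P01 array 1; 0.33) and smooth muscle (P01 arrays 2 and 3, P07 array 3; 0.33 to 0.42). Quantile normalization ended the calls of leukocytes (0.05), amino acid and glucose metabolism (0.11), smooth muscle (0.39), Cubn (0.72) and Slc22a30 (0.57). The most variable probe ended those of amino acid and glucose metabolism (0.28), smooth muscle (0.39), Rpl13 (-0.62) and Slc22a30 (0.87), and zeros kept as ratios that of H2-Aa (1.53). Slc22a30 did not pass with array weights (0.52) or the image month as a block (0.78) either. With Xist as a covariate Cnn1 (1.20), Rpl13 (-0.59) and Slc22a30 (0.92) did not pass.

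For P07 minus P01, 1237 of 16737 genes passed (809 up, 428 down), 1763 with the block and 1071 of them shared. The count was 124 with only these 2 stages compared and 2015 with array weights. With Xist as a covariate, chosen after seeing the data, 995 passed, 910 of them among the 1237. Xist was high on all P01 arrays and, at P07, on array 1 alone. Non-overlapping arrays were found for 21.4% of genes, where chance gives 10.0% for genes measured on all these arrays. The count was 739 and 769 without P01 arrays 2 and 3, and 732 without P07 array 2. Of the 15 called lists all but the leukocyte and smooth muscle lists were called with the block.

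**Figure D3:**
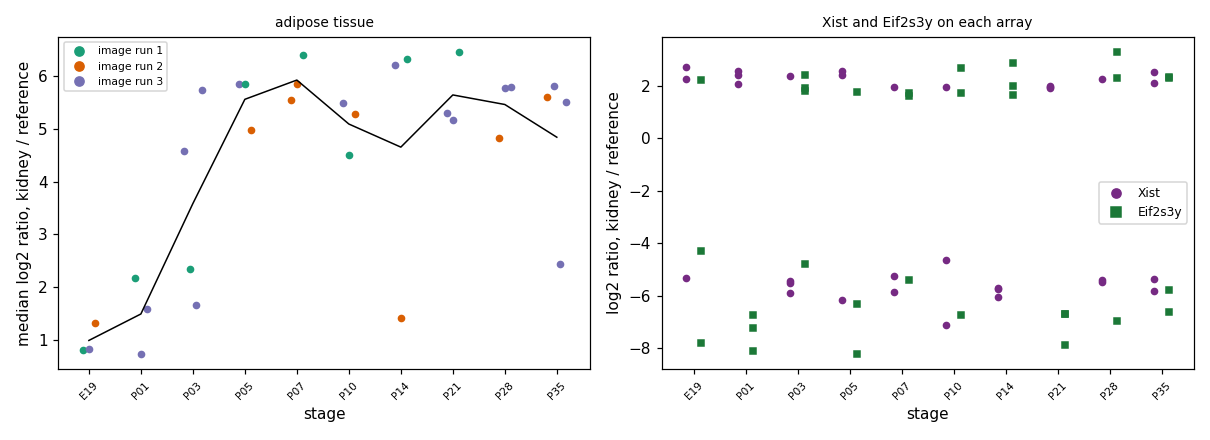
Median log2 ratio of the adipose list on each array (points by image run), and log2 ratios of Xist and Eif2s3y on each array, by stage. The adipose median lay between 0.81 and 1.32 at E19, and P14 array 2 (1.42) and P35 array 3 (2.44) lay below the other arrays of their stages.

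From P07 to P21, cell division and matrix genes fell and oxidative phosphorylation genes rose. Of 29 cell cycle genes 25 fell (29 adjusted over the list alone, median -1.35, -1.29 with the block, adjusted p = 1.14e-19), with Mcm4 (-1.61 ± 0.22) and Mcm6 (-1.70 ± 0.24), of the replicative helicase. Of 21 oxidative phosphorylation genes 18 rose (20 adjusted over the list alone, median 0.91, adjusted p = 5.95e-12), with Ndufs1 (1.10 ± 0.22) and Uqcrc2 (0.91 ± 0.18). Of 23 matrix genes 11 fell (15 adjusted over the list alone, median -0.91, adjusted p = 1.98e-09), with Col1a1 (-1.88 ± 0.26) and Col3a1 (-1.60 ± 0.21). The largest falls were Cstdc6 (-6.10 ± 0.79), Nts (-5.65 ± 0.78), Kcnmb4 (-5.63 ± 0.47), Afp (-5.57 ± 0.36) and Unc5cl (-5.46 ± 0.35). The largest rises were Tprg (5.59 ± 1.02), Gys2 (4.88 ± 0.43), a glycogen synthase, Retnla (4.69 ± 0.84), Slco4c1 (4.41 ± 0.58) and Hpd (4.35 ± 0.84), which degrades tyrosine. The adipose list had a median of -0.14 and 0 of 8 genes past limma's test (adjusted p = 0.936).

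Of 14 imprinted genes 8 fell (10 adjusted over the list alone, median -1.14, adjusted p = 3.72e-10), with Mest (-3.52) and Igf2 (-3.46). Of 11 stromal genes Aldh1a2 (-2.07), Penk (-2.39), Fibin, Meis1 and Foxd1 fell (6 adjusted over the list alone; -0.76, adjusted p = 0.000254). Of 19 amino acid and glucose genes 8 rose on either adjustment (0.66, adjusted p = 2.67e-07), with Prodh (3.10) and Khk (1.41), and of 21 fatty acid oxidation genes 6 did (0.33, adjusted p = 0.00119). These and the 3 lists before them passed with an estimated correlation. Of 23 xenobiotic genes 6 rose on either adjustment (0.60, adjusted p = 0.000131), with the glutathione transferases Gstm1 (1.92) and Gstm3 (2.03). Of 13 interferon-induced genes Ifit3 (1.55), Oas1a (0.89), Ifit1 and Usp18 rose (5 adjusted over the list alone; 0.71, adjusted p = 0.000559). Of 10 ureteric bud tip genes 4 fell and Slco4c1 rose (6 and 1 adjusted over the list alone; -1.08, adjusted p = 0.0183). Of 15 ribosomal protein genes 4 fell (5 adjusted over the list alone; -0.44, adjusted p = 0.00892). With an estimated correlation these 4 calls were not kept (adjusted p = 0.157, 0.157, 0.0833 and 0.20). The ribosomal call also ended without P07 array 3 (-0.40) and after quantile normalization (-0.28).

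Tubule lists had few genes past the test in this span. On either adjustment 5 of 37 proximal tubule genes rose (median 0.24, adjusted p = 0.00227), Slc12a1 and Egf of 12 in the thick ascending limb (0.30, adjusted p = 0.0196), Cnnm2 and Ppp1r1b of 11 in the distal convoluted tubule (0.59, adjusted p = 0.0158), and Slc6a12 and Slc5a3 of 8 in urea and osmolyte handling (0.55, adjusted p = 0.0448). With an estimated correlation none was called (adjusted p = 0.509, 0.327, 0.461 and 0.225), and the last was not called with the block (adjusted p = 0.0644). The first 3 also lost the call without P07 array 1 (0.03, 0.09 and 0.45) or P21 array 3 (0.08, 0.09 and 0.41). The last lost it without P07 arrays 2 or 3, P10 arrays 1 or 2, P21 array 3 or P35 array 1 (0.40 to 0.55), after quantile normalization (0.54), with the most variable probe (0.53), with Xist (0.54) and with the adipose covariate (0.55). The thick ascending limb call ended after quantile normalization (0.29). Smooth muscle genes Acta2 (-1.37), Notch3 and Pdgfrb fell, of 10 (5 adjusted over the list alone; -0.46, adjusted p = 0.0176, adjusted p = 0.456 with an estimated correlation; not called without P07 array 3, -0.33). In lists without a call, Acta1 (-1.98) of skeletal muscle and Chga (-1.53) fell and Cd74 (1.15), Krt15 (2.08), Nr1d1 (0.92) and Cyp4b1 (1.27) rose. Klf1 (1.14) and Jun (-1.05) passed but not with the block (0.81, adjusted p = 0.0651, and -0.73, adjusted p = 0.0731). Without 1 array Chga (P07 array 3, P21 arrays 1 and 3; -1.49 to -1.41), Cyp4b1 (P07 array 1; 0.79), Jun (P07 array 2, P21 arrays 1 and 3; -1.01 to -0.53) and Klf1 (P07 array 2, P21 array 3; 1.09 to 1.12) did not pass. Jun also lost its call after quantile normalization (-0.86), with the image month as a block (-0.97) and with Xist (-0.99), and Chga with Xist (-1.38).

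For P21 minus P07, 2587 of 16882 genes passed (1055 up, 1532 down), 3408 with the block and 2290 of them shared. It was 1635 with only these 2 stages and 3768 with array weights. With Xist as a covariate, chosen after seeing the data, 2457 passed, 2259 of them among the 2587. Xist was high on all P21 arrays and mixed at P07. Non-overlapping arrays were found for 32.9% of genes, where chance gives 10.0% for genes measured on all these arrays. Of the 16 called lists all but urea and osmolyte handling were called with the block.

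From P21 to P35 few genes passed. Nat8f5 (8.17 ± 1.06, n = 2 at P21), Akr1c14 (6.78 ± 0.78), Ces1g (5.47 ± 0.90), a carboxylesterase, Slc22a26 (5.04 ± 0.50), an organic anion transporter, and Akr1c18 (3.85 ± 0.44), which inactivates progesterone, rose most. Mro (-4.60 ± 0.74), Serpina6 (-3.98 ± 0.51), the corticosteroid-binding globulin, Hdc (-2.99 ± 0.63), which makes histamine, Slc10a1 (-2.42 ± 0.46), a bile acid transporter, and Cbr1 (-2.30 ± 0.36) fell most. Of 10 male-biased genes Cyp2j13 (2.35 ± 0.53) and Cyp4a12a (1.23 ± 0.28) rose (5 adjusted over the list alone, median 0.56, 0.66 with the block, adjusted p = 0.00125, adjusted p = 0.125 with an estimated correlation). Sex is not labelled. Xist, transcribed from the inactive X chromosome, lay between 1.92 and 1.98 on the 3 P21 arrays, and at 2.12, -5.81, 2.51 and -5.36 on P35 arrays 1 to 4. On those 4 arrays in turn Cyp2j13 lay at 4.29, 6.45, 5.12 and 5.71 and Cyp4a12a at 3.03, 4.35, 3.74 and 4.75. Members of the list differed in their order over these arrays. Cyp2j13, Cyp4a12a, Acsm3, Odc1, Slc7a13 and Cyp4b1 were higher on both low-Xist arrays than on both high-Xist arrays. Cyp2d9 showed the reverse, and Kap, Slco1a1 and Slc22a30 were mixed. Acsm3 lay at 5.09, 8.94, 6.29 and 8.61 and Cyp2d9 at 4.50, 4.28, 4.76 and 3.94. Slc22a30 lay at 6.00, 6.17, 6.34 and 6.01. At P28, Xist was low on arrays 1 and 2 and high on array 3. All members but Slco1a1 and Cyp2d9 were higher on P28 arrays 1 and 2, such as Cyp2j13 (6.27 and 6.23 against 2.93). These orders and examples were chosen after their values were seen and were not tested. Cyp2j13 did not pass with Xist as a covariate (2.03) or with exact zeros kept as ratios (2.59), both chosen after seeing the data. Its rise followed a fall of -1.96 from P07 to P21 (from 5.00 to 3.04), a span in which its probes passed in opposite directions.

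Of 23 matrix genes Sparc (-0.94) and Col4a1 (-0.84) fell (7 adjusted over the list alone, median -0.51, -0.50 with the block, adjusted p = 5.60e-08). Of 12 clock genes 0 passed limma's test (5 up adjusted over the list alone; 0.31, adjusted p = 0.0214). These 2 lists also passed with an estimated correlation. Of 21 fatty acid oxidation genes Acadm (1.25) rose (2 adjusted over the list alone; 0.23, adjusted p = 0.00519), and of 14 imprinted genes Mest (-0.90) fell (1 up and 2 down adjusted over the list alone; -0.35, adjusted p = 0.00831). Of 10 smooth muscle genes Tagln (-0.91) fell (3 adjusted over the list alone; -0.63, adjusted p = 7.11e-05). Slc6a12 (-2.13), an osmolyte transporter, fell of 8 (-0.42, adjusted p = 0.0241) and Penk of 11 stromal genes (-0.36, adjusted p = 0.0280), both also adjusted over the list alone. Immediate early genes had 0 of 13 past limma's test (-0.40, adjusted p = 0.0185), leukocytes 0 of 17 (0.19, adjusted p = 0.0448) and the cell cycle 0 of 29 (-0.18, adjusted p = 0.0473), also adjusted over the list alone. Of 23 xenobiotic genes Nat8 and Cyp4a12a rose on either adjustment (median 0.01, mean 0.25, adjusted p = 0.0453). With an estimated correlation these 9 calls were not kept (adjusted p = 0.0523, 0.0825, 0.157, 0.164, 0.157, 0.327, 0.453, 0.712 and 0.533 in the order given). The adipose list had a median of -0.40 and 0 of 8 genes past limma's test (adjusted p = 0.609).

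Single arrays decided several of these calls. Without any P21 array, P35 array 2 or P35 array 4, Col4a1 (-0.91 to -0.76), Cyp2j13 (2.00 to 2.55), Cyp4a12a (0.97 to 1.28) and Tagln (-0.96 to -0.78) did not pass. The same held for Hdc without P21 arrays 2 or 3 or P35 arrays 2 or 4 (-2.88 to -2.35), Mest without P21 arrays 1 or 2 (-0.86 to -0.76) and Slc10a1 without P21 array 3 (-2.19). List calls ended for clock genes (P21 arrays 1 and 2, P35 array 1; 0.31 to 0.33), immediate early genes (P21 array 3; -0.35), stromal progenitors (P21 array 3, P35 array 4; -0.38 to -0.33) and urea and osmolyte handling (P21 array 3, P35 array 4; -0.54 to -0.45). They ended for leukocytes without P10 array 1, P21 arrays 1 or 2 or P35 array 1 (0.13 to 0.25). For the cell cycle 16 single arrays ended the call, among them P21 arrays 2 and 3 and P35 arrays 2 and 3 (-0.22 to -0.04), and for xenobiotic metabolism 9, among them P21 arrays 1 and 2 and P35 arrays 2 and 3 (-0.08 to 0.05). Quantile normalization ended the calls of the cell cycle (-0.06), fatty acid oxidation (0.17), immediate early genes (-0.28), xenobiotic metabolism (-0.06) and Tagln (-0.77). The most variable probe ended those of the cell cycle (-0.16), urea and osmolyte handling (-0.47) and Col4a1 (-0.67). Xist as a covariate ended those of stromal progenitors (-0.34), xenobiotic metabolism (-0.03) and Col4a1 (-0.79). The cell cycle call also ended with array medians subtracted (-0.18) and with the adipose covariate (-0.17), and the leukocyte call with zeros kept as ratios (0.19).

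For P35 minus P21, 152 of 17230 genes passed (84 up, 68 down), 380 with the block (173 up, 207 down), of which 151 were shared, and 102 changed at least 2-fold (71 up, 31 down). With only these 2 stages compared 4 passed, within image run 3 29 did, 20 of them among the 152, and with array weights 1184. Non-overlapping arrays were found for 14.7% of genes, where chance gives 5.71% for genes measured on all these arrays. The count was 70, 60 and 51 without P21 arrays 1, 2 and 3, 74 and 91 without P35 arrays 2 and 4, and 237 without P35 array 1. With Xist as a covariate, chosen after seeing the data, it was 101, and 96 of those were shared. The 12 called lists were all called with the block.

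The timing of change was described for 3123 of the 7138 genes (43.7%), those for which a single step between neighbouring stages reached an R squared of 0.6. Of 1487 rising genes 64.4% (95% exact binomial interval 61.9 to 66.9) and of 1636 falling genes 78.7% (76.7 to 80.7) had the step between P10 and P14 or later, 64.6% and 75.0% with the block. The intervals cover counting error of independent genes only, and with 1 array left out the shares ran from 59.2% (without P10 array 2) to 67.8% (without P14 array 1) and from 75.4% to 80.6% (without the same arrays). All 29 cell cycle genes had a falling step, 28 of them late, and all 12 matrix genes with a step fell late. All 8 nephron progenitor genes with a step fell and 0 did so late, a count with no test. Of 13 proximal tubule genes with a rising step 3 were late, and of 17 oxidative phosphorylation genes 11. The best-fitting steps were Cyp4a14 (5.34) and Bst2 (-1.34) over birth, Aoah (2.14) and Traf1 (-2.06) before P03, Iqcg (1.24) and Eya1 (-3.39) before P05, and Siae (1.25) and Kif5c (-2.52) before P07. They were Serpinb8 (2.34) and Fibin (-2.74) before P10, Aspg (2.41) and Megf10 (-3.58) before P14, Prodh (2.90) and Tpst1 (-1.69) before P21, Cyp2a4 (3.47) and Col4a1 (-1.34) before P28, and Rhox6 (3.85) and Serpina6 (-3.60) before P35.

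**Figure D4:**
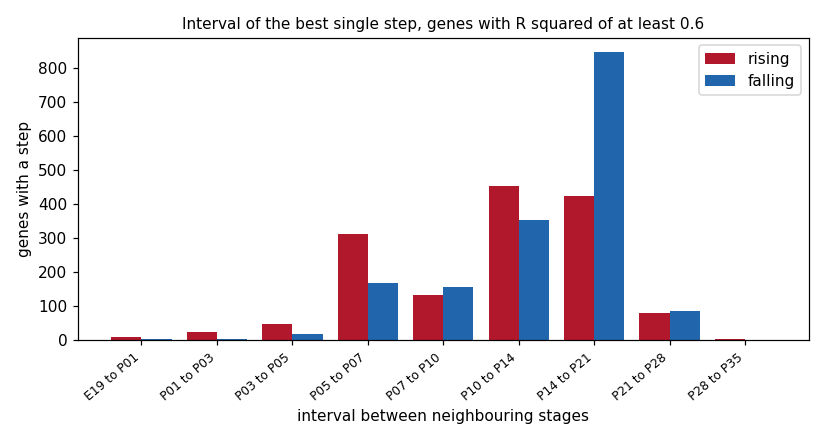
Number of genes with their best single step in each interval between neighbouring stages, rising and falling, as bars. The tallest bars are 452 rising genes from P10 to P14 and 847 falling genes from P14 to P21.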

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

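The tests of a change with stage alone, of unequal sex and of the image run, in the patterns below, were chosen after the result was seen, and the others before.

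Genes of brown and white fat were higher at P07 than at P01, with a median log2 change of 4.33 for the adipose list, and they differed between arrays of the same stage. The image run is argued against by the median of 4.70 that remained with the run as a block. A change with stage alone stays open for the rise itself, since the list median ranged over 1.44 at P01 and 0.85 at P07, less than the change. Within other stages the median ranged over 4.91 at P14, 4.07 at P03 and 3.37 at P35. These ranges argue against stage alone for the differences between arrays of the same stage. Fat attached to some kidneys is a candidate source: a further list of 10 brown fat genes, written after the rise was seen but before its own values were, had a median change of 1.11 against a bound of 1 set beforehand, although only Slc36a2 (3.75) and Cox7a1 (1.43) passed and Tshr was at -1.21. The abundant genes Adipoq and Ucp1 reached log2 ratios of 5.52 and 6.36 at P07, whereas Fabp4 changed by 0.06 from an already high 6.34, 0 of the 10 adipose genes are in another list, the labels name no sort or gate, and expression by kidney cells stays open too.

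Between P21 and P35, 152 genes passed, while all P21 arrays had high Xist and P35 arrays were mixed. The image run as the cause is argued against by the 151 genes that also passed with it as a block. Unequal sex of the animals stays open: with Xist as a covariate, which removes only a difference that is equal at all stages, 101 genes passed and 96 of the 152 were among them. Sex differences that arise only after P21 stay open too. Age itself was not tested apart from these. Xist was also unevenly high between E19 and P01, between P01 and P07 and between P07 and P21. Unequal sex therefore stays open for those spans too. With Xist as a covariate 230 genes passed for P01 minus E19, 215 of them among the 246. E19 and P35 arrays were both mixed, in unequal shares, so it stays open for P35 minus E19 as well. There 6810 genes passed with Xist as a covariate, 6687 of them among the 6883.

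Steps were concentrated from P10 to P14 and from P14 to P21, which held 66.4% of all steps and 65.1% with the image run as a block, a value that argues against the run as the cause. Gradual change over unequally spaced stages may account for much of the pattern: a straight line over days fitted at least as well as the step for 58.2% of these 2075 genes (median R squared 0.746 for the line and 0.72 for the step). In simulated data 86.2% of the steps kept for such lines were placed there too. Abrupt change in the other genes stays open as a biological hypothesis. Xist was low on all P14 arrays and high on all P21 arrays. Step timing was not computed with Xist as a covariate, so a part of unequal sex in this pattern was not tested.

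Other splits of the arrays were counted for each number of genes past the test. Of 100 assignments of the 32 arrays to stages, 1, the real one, gave as many as 7138 genes. That share of 0.01, the smallest that 100 assignments can give, argues against chance among assignments that ignore the image run. The highest of the 99 others gave 2342 (median 0), a maximum that varies with the draw. For P35 minus E19 1 of 35 splits gave as many as 6883, and for P35 minus P21 1 of 35 gave as many as 152. These shares, 0.0286 each, are under the bound of 0.05 set beforehand and are the smallest that 35 splits can give. They ignore the image run and are not adjusted over the counts tested, so they do not exclude chance. For P35 minus E19 the highest other, the real split with P35 array 1 moved to the E19 side, gave 4983, and for P35 minus P21 the highest other, with the same array moved to the P21 side, gave 134. For P01 minus E19, P07 minus P01 and P21 minus P07 the 10 splits are too few for a share under 0.05: the real values, each reached by 1 split, were 246, 1237 and 2587, and the highest others 1, 0 and 0.

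Among 124 groups of 4 arrays, 9 had an array far from the others, where chance gives about 1 in 20. The 9 are thus near the number that chance gives, and the groups overlap, since Retn belongs to the adipose list. At P03, array 2 had medians of 5.29 for intercalated cells (others 3.84 to 4.05) and 4.64 for the renin-angiotensin system (others 3.83 to 3.88). At P35, array 3 had medians of 2.44 for adipose tissue (others 5.52 to 5.81) and 4.15 for vitamin D and phosphate hormones (others 3.65 to 3.71), Retn at 0.66 (others 2.74 to 3.08) and Cyp4a14 at 8.98 (others 8.06 to 8.16). At P35, array 4 had an oxidative phosphorylation median of 2.59 (others 2.04 to 2.07), Khk at 3.84 (others 4.13 to 4.17) and Dbh at -0.078 (others 0.26 to 0.30). Among probes without a listed gene, which the comparisons leave out, 1635 of 7503 (21.8%) changed between E19 and P35, 770 up and 865 down.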

How the results depend on the processing

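The alternatives with exact zeros kept as ratios, Xist as a covariate and the adipose list as a covariate were chosen after seeing the data. Where no cause is named, the cause was not tested. No named gene that passed reversed under any alternative, and of 75 list calls 1 reversed: the adipose list itself for P07 minus P01 with its own median as a covariate (0.48), which follows from the construction. Of 75 list calls 74 were the same with array medians subtracted, 74 with zeros kept, 71 with the image run as a block, 71 with Xist, 68 with the most variable probe, 67 with the adipose covariate and 59 after quantile normalization, and apart from that reversal the rest lost the call. Of 168 named gene results 163 were the same with the run block, 2 lost the call and 3 gained it, with array weights 2 lost it and 15 gained it, and 20 lost it with the adipose covariate, 12 with a minimum of 2-fold, 9 with Xist, 5 after quantile normalization and 55 with only the 2 stages compared. With 1 array left out 5232 of 5364 named gene results and 2316 of 2400 list results were the same.

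Quantile normalization gave 380 genes for P01 minus E19 and 72.1% late falling steps. With only the 2 stages compared, fewer arrays estimate the spread, and limma gave 0 genes for P01 minus E19 (1437 at an unadjusted p under 0.05), 124 for P07 minus P01, 1635 for P21 minus P07 and 4 for P35 minus P21. The run block gave 681 for P01 minus E19, 380 for P35 minus P21 and 75.0% late falling steps, and the image month 410 and 317. Within run 2 limma gave 0 genes across all stages and 0 for P35 minus E19 (3335 unadjusted), with 1 residual degree of freedom. Within run 3, with 1 E19 array, there were 80 for P01 minus E19 (29 up, 51 down), of which 25 were among the 246, and 29 for P35 minus P21 (17 up, 12 down), of which 20 were among the 152. Run 1 left no residual degrees of freedom, so it gave values without a test. Array weights, from 0.343 to 6.01, gave 12370 across all stages, 2847 for P01 minus E19, 2015 for P07 minus P01 and 1184 for P35 minus P21. Single arrays dominated some stages. E19 array 3 had a weight of 4.37 against 0.939 and 0.343, and P14 array 2 had 6.01 against 0.685 and 0.524. The weighted counts therefore rest in part on few arrays. A minimum of 2-fold, which can only remove genes, left 4475 for P35 minus E19, 714 for P07 minus P01 and 1585 for P21 minus P07. Xist as a covariate gave 101 for P35 minus P21 and the adipose list 269 for P07 minus P01.

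An estimated correlation left 10, 3, 5, 7 and 2 called lists of 21, 11, 15, 16 and 12. Late steps were 61.7% rising and 74.9% falling at R squared 0.5, 67.6% and 82.1% at 0.7 (1626 genes), and 58.7% and 71.5% from stage means (6203 genes). Leaving out each array gave 6746 to 7506 genes across all stages, 5917 to 6966 for P35 minus E19, 53 to 260 for P01 minus E19, 732 to 1303 for P07 minus P01, 1771 to 2652 for P21 minus P07 and 51 to 237 for P35 minus P21. The lowest were without P35 array 2, E19 array 1, P01 array 3, P07 array 2, P07 array 2 and P21 array 3, in that order. Called lists were 18 to 21, 9 to 12, 12 to 18, 12 to 16 and 8 to 12, late steps 59.2% to 67.8% rising and 75.4% to 80.6% falling, and genes with a step 2883 to 3371. Signal over background could not be assessed from ratios.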

Other observations

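No test was added here. The values below are descriptive, and the genes were chosen after their values were seen. The angiotensin receptors moved in opposite directions over the series: Agtr2 had a mean log2 ratio of 3.17 ± 0.48 (SD, n = 3) at E19, 1.04 at P07 and -2.55 ± 1.15 (n = 4) at P35, while Agtr1a went from 3.55 ± 0.30 at E19 to 4.78 at P01 and 4.91 ± 0.23 at P35. Cd74, the invariant chain of antigen presentation, lay at -2.28 ± 0.17 at E19, -0.56 at P21 and 0.11 ± 0.29 at P35. Isg15, a ubiquitin-like protein induced by interferon, lay at -0.59 ± 0.36 at E19, -2.78 ± 0.17 at P01 and -1.25 at P21. Afp held between 3.51 and 4.63 up to P10, was at 1.17 ± 0.86 at P14 and at -1.36 ± 0.18 at P21.

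The erythroid and podocyte lists had no call in any of the 5 spans tested, so their values are only described. The median of the erythroid list was 1.81 ± 0.23 (SD, n = 3) at E19, 0.59 at P01, 2.82 ± 0.61 at P10 and 1.43 ± 0.44 (n = 4) at P35. That of podocytes was 2.01 ± 0.40 at E19, 2.66 ± 0.39 at P07 and 1.45 ± 0.55 at P35. The clock list, called for P35 minus P21 alone, was at -1.22 ± 0.25 at E19 and 0.09 ± 0.08 at P35. The labels do not give the time of day of sampling, so its part could not be checked.

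Genes measured on every array of 1 stage and on none of the other were left out of the test: 9 on every P35 array and no E19 array, such as Slc16a14 (4.83 ± 0.51) and Mbl1 (4.39 ± 0.65), and 18 the reverse, such as Adamts19 (5.02 ± 1.46) and B3gnt5 (3.76 ± 0.66). In all, 1882 genes had fewer than 2 measured arrays at E19 or P35. Xist was high on all P01 and P21 arrays, low on all P14 arrays (-6.04 to -5.71) and mixed at the other stages, and Eif2s3y, a Y-linked gene, was above 0 wherever Xist was below 0. Probes without a listed gene changed in 65, 247, 400 and 8 cases in the 4 shorter spans.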
